A study of Mus musculus with 6 samples.

How the data were processed

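Whole liver RNA was measured in 6 libraries, 3 from untreated control mice and 3 from tamoxifen-treated mice with an endothelial deletion of TAK1. Per the labels' protocols, libraries were made with the TruSeq Sample Prep v2 kit and sequenced as paired ends on an Illumina HiSeq instrument. Per the submitters' processing notes, the tools were Trimmomatic 0.33, TopHat2 2.1.0, Cuffdiff 2.2.1 and Cuffnorm 2.2.1 with genome build mm9; the gene annotation is not given in the sources used here. The deposited table holds FPKM values per gene, 1 column per library, and the authors' values were used as they stand. FPKM divides a gene's fragments by its transcript length and by the library's mapped fragments, so a gene that fails to be estimated, or a few very abundant genes, can shift every other value.

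The table has 24318 rows, of which 8986 are at 0 in every library. Row names were used as gene symbols. 27 rows carry names turned into dates by a spreadsheet, and these were tested but are never named. Alb was at 0 in all controls and above 1000 FPKM on average in knockouts, and was left out as a failed estimate. No counts are given, so no count model was used and no counting interval can be given. Absolute depth is unknown, and the relative depths below assume that each library was scaled by its own mapped fragments. Low values that lie on steps of up to 4 fragments within 0.01 log2 units of a whole step (73.8% to 77.2% of the low values compared, depending on the library) gave relative depths of 0.964 and 1.08 for controls 2 and 3 and 1.04, 0.936 and 0.921 for knockouts 1, 2 and 3, against control 1. The 10 most abundant genes other than Alb took 19.3% to 20.1% of the summed FPKM in controls and 25.7% to 32.7% in knockouts.

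Knockout was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided) on log2(FPKM + 0.5), for the 11842 genes with a mean of at least 0.5 FPKM over the 6 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Of 44 gene lists fixed beforehand, 41 had at least 5 measured members and were tested with limma's camera (preset correlation 0.01) and, as alternatives, with an estimated correlation and with fry. Named genes followed a rule written before the data were examined, as were the lists, the tests and the alternatives other than 3 named below. The rule takes Map3k7 and Cdh5; the 12 largest rises and 12 largest falls among called genes that reach 5 FPKM in the higher group and whose groups do not overlap, predicted genes excluded; and, per list, up to 4 called members with the largest change, or the 2 most abundant where fewer than 2 are called. Not every gene the rule takes is named or drawn, and those whose call was lost without a library were mostly left out in favour of others. Means that moved by over 1.5 times without 1 library are given with that mean. Genes named after their values were seen were not run under the alternatives. Map3k7 and Cdh5 were also tested by exact permutation. Their places are from GENCODE on GRCm38, which is not the authors' build; transcript length and GC content, also from GRCm38, matched 98.4% of rows. Figures were drawn with matplotlib 3.10.9.

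The replicates are labelled only as triplicates, so p-values measure the spread between these samples. Spearman correlations were 0.960 to 0.963 within a group and 0.937 to 0.951 between groups, and no pair of libraries shared a nonzero value. In simulated data on 11610 genes of this comparison, 52% of 100 genes changed by 1 log2 unit and 93% of 100 changed by 2 were recovered. There were 9 false calls among 11417 unchanged genes. The moved list was called, as was 1 unmoved list among 41 run. The simulated noise was independent between genes, whereas estimated correlations within the lists reached 0.89 (cholesterol synthesis). These false calls therefore do not measure the error of the tests on the real data. The alternatives were other pseudocounts, filters and scalings, other variance models, library weights, a replicate block and each library left out in turn. Chosen after seeing the data were the retention of Alb, the removal of genes at 0 in any library, and a correction for transcript length and GC content.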

Results

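The data were gene expression values of whole livers from mice in which the kinase TAK1, encoded by Map3k7, can be deleted in endothelial cells. The mice carried loxP-flanked Map3k7 alleles and a tamoxifen-inducible Cre recombinase driven by the promoter of Cdh5, the gene of VE-cadherin. Knockout livers came from tamoxifen-treated mice and control livers from untreated mice of the same genotype, with 3 libraries in each group. Knockout and tamoxifen therefore cannot be separated in any comparison. Libraries were sequenced as paired ends, and the values are FPKM, fragments scaled by transcript length and library size. Total read numbers are unknown. If each library was scaled by its own mapped fragments, steps between low values put the depth of the libraries at 0.921 to 1.08 times that of control 1. Values below are mean ± SD over the 3 libraries of a group, and log2 fold changes of knockout against control are on the log2(FPKM + 0.5) scale, which understates changes of low genes, with their standard error. Where a gene whose level or change is given is listed at 0 in some library, the library values or their range are given. Genes used by every cell, such as Eno1, were also listed at 0.

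The comparison asks how the liver's transcripts differ after endothelial deletion of TAK1. Map3k7 itself (ENSMUSG00000028284, chromosome 4, 31964097 to 32023467 in GRCm38) measured 8.498, 9.02 and 9.14 FPKM in the control libraries and 9.28, 9.31 and 7.35 FPKM in the knockout libraries. Its log2 fold change -0.04 ± 0.16 did not pass the test (limma adjusted p = 0.868), and the exact two-sided permutation p was 1, with 0.1 the smallest that 3 against 3 libraries can give. Cells other than endothelium also express Map3k7, and transcripts that lack only the loxP-flanked part still count towards the gene, so this value does not check the labels. Cdh5 (ENSMUSG00000031871, chromosome 8, 104101625 to 104144511) measured 12.7, 10.3 and 23.1 FPKM in control and 18.8, 18.0 and 16.3 FPKM in knockout libraries, with a log2 fold change 0.28 ± 0.26, adjusted p = 0.469 and an exact permutation p of 0.6. Without control 3 the log2 fold change of Cdh5 was 0.61 and adjusted p = 0.0349, in a range of 0.0349 to 0.928 over all alternatives. Among 20 measured genes of the TAK1 complex and its pathway, Xiap, an inhibitor of apoptosis, was the only one past the threshold (log2 fold change 0.57 ± 0.18, adjusted p = 0.0449), and its call was lost without any 1 library but knockout 3, with log2 fold changes of 0.43 to 0.61. Xiap also did not pass under 4 alternatives with all 6 libraries (adjusted p of 0.0575 to 0.144). The pathway's most abundant members, Mapk14 and Rela, had log2 fold changes of -0.02 and 0.22, and the list was not shifted. TAK1 pathway genes numbered 0 higher and 0 lower adjusted over the list alone, with a camera adjusted p = 0.834 and an adjusted p = 0.84 with an estimated correlation.

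Knockout livers had more RNA of many myeloid and acute phase genes, and less of many genes of sinusoidal endothelium and hepatocyte metabolism. As lists, neutrophil genes kept their call with an estimated correlation (adjusted p = 0.0445), while acute phase (0.0963), sinusoidal (0.225), pericentral (0.0914) and cholesterol synthesis genes (0.294) did not. Igfbp1, a secreted hepatic binding protein of insulin-like growth factors, rose from 22.1 ± 10.97 to 1527 ± 977 FPKM (970.0 without knockout 2, adjusted p = 7.51e-05). The acute phase apolipoprotein Saa3 rose from 102 ± 68.5 (63.3 without control 3) to 3147 ± 1122 FPKM (adjusted p = 9.65e-05). The calgranulins S100a8 and S100a9 of neutrophils rose from 24.4 ± 16.7 (14.8 without control 3) to 716 ± 20.3 FPKM and from 22.5 ± 5.74 to 691 ± 44.7 FPKM. Largest among the falls were the sinusoidal lectin Clec4g, at 44.4, 63.8 and 56.5 FPKM in control and 0.381, 0 and 0 in knockout libraries, and the carbonic anhydrase Car3, which fell from 432 ± 73.1 to 9.999 ± 6.23 FPKM (adjusted p = 9.88e-05, log2 fold change -5.61, and -4.94 without knockout 2).

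Other large rises were those of Chil3 (0 to 0.308 FPKM in control and 51.1 to 78.0 in knockout libraries), the antimicrobial granule genes Camp (0 to 0.989 and 44.5 to 60.2), Ngp (0 to 4.34 and 102 to 139.7) and Ltf (0 to 0.327 and 24.1 to 35.0), the neutrophil gene Retnlg (log2 fold change 5.59 ± 0.29, adjusted p = 9.79e-06), the eosinophil major basic protein gene Prg2 (0 to 1.18 and 38.6 to 68.5) and the fatty acid receptor Ffar4 (0 to 0.358 and 20.2 to 29.9). Large falls were those of the endothelial lipase anchor Gpihbp1 (21.1 to 33.2 FPKM in control and 0 to 1.96 in knockout libraries), the clock output gene Dbp (log2 fold change -4.16 ± 0.30, adjusted p = 5.18e-05), the corticosteroid-binding globulin gene Serpina6 (log2 fold change -3.97 ± 0.36, adjusted p = 1.67e-04), Tlcd2 (log2 fold change -3.68 ± 0.43, adjusted p = 4.59e-04, and -3.09 without knockout 2), the lipogenic regulator Thrsp (log2 fold change -3.67 ± 0.28, adjusted p = 6.32e-05) and the uridine phosphorylase Upp2 (log2 fold change -3.65 ± 0.39, adjusted p = 3.19e-04). Gsta2 measured 11.7, 36.6 and 12.04 FPKM and Rpph1 11, 17.3 and 10.5 FPKM in control libraries, and both were listed at 0 in all knockout libraries. Such zeros can be failed estimates, and Gsta2 has close paralogs that can share its reads. The albumin gene Alb was listed at 0 in every control library and at 59068, 73306 and 55705 FPKM in the knockout libraries, and was left out as a failed estimate.

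**Figure D1:**
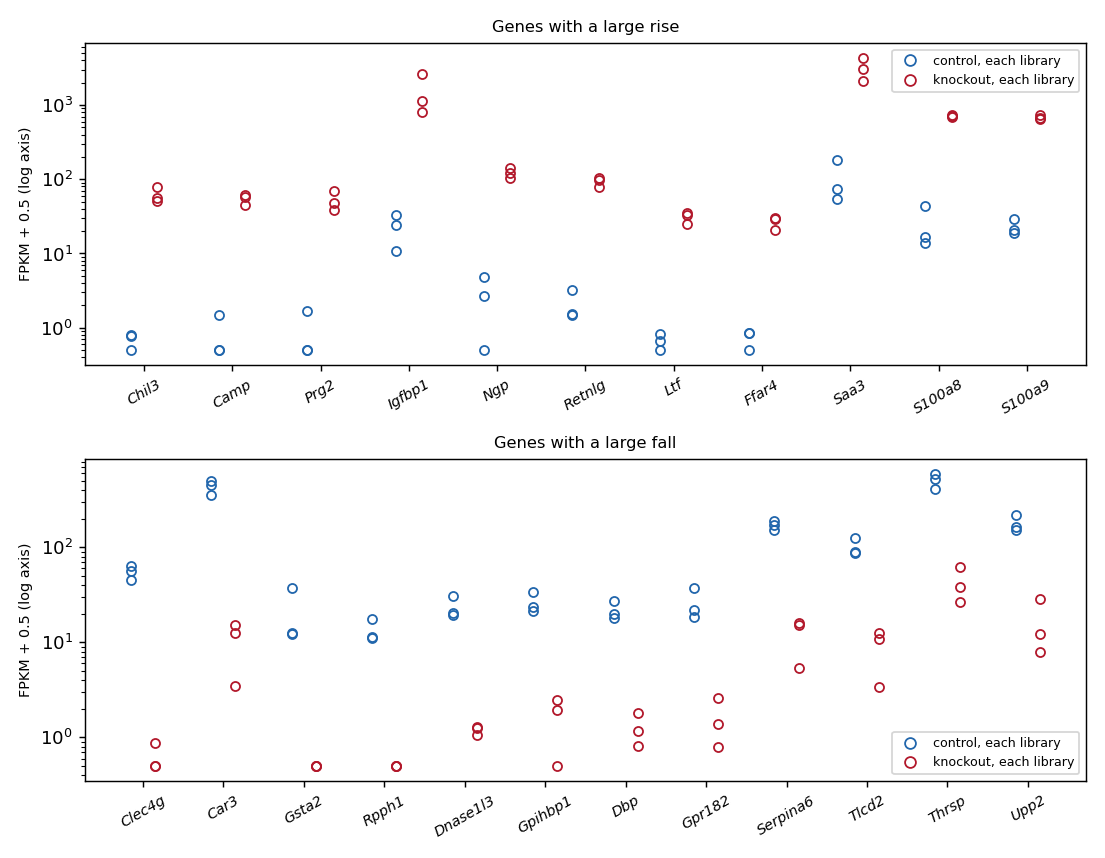
FPKM + 0.5 on a log axis in each of the 3 control (blue) and 3 knockout (red) libraries for genes with a large rise and genes with a large fall taken by the rule for named genes. Igfbp1 lies at 10.4 to 32.2 FPKM in control and 808 to 2639.8 FPKM in knockout libraries, and the groups do not overlap for any gene shown.

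In total, 1669 genes were higher and 1534 lower in knockout livers among 11842 tested (limma, Benjamini-Hochberg adjusted p under 0.05), of which 1124 and 602 differed by at least 1 log2 unit. The groups did not overlap for 43.5% of tested genes, where chance gives 10%. Calls were 52.1% higher with the deposited scaling, and 39.5% higher (1354 against 2076) once each library was rescaled to the same total, which moved the median log2 fold change of all genes from -0.0007 to -0.10. Without control 1 the lower genes numbered 996, and without control 2 they numbered 943.

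Many endothelial genes fell. Of 25 measured genes shared by most endothelial cells, 16 fell and none rose, with a median log2 fold change of -1.16. General endothelial genes numbered 1 higher and 16 lower adjusted over the list alone, with a camera adjusted p = 1.76e-05 and an adjusted p = 0.233 with an estimated correlation. The receptor phosphatase Ptprb fell from 7.05 ± 2.94 to 0.371 ± 0.0487 FPKM (adjusted p = 2.03e-04). The VEGF receptor Kdr fell from 12.3 ± 5.33 to 1.38 ± 0.320 FPKM (adjusted p = 3.75e-04). The adhesion receptor Adgrf5 had a log2 fold change -1.90 ± 0.28 and the tight junction gene Cldn5 a log2 fold change -1.80 ± 0.33. Of 24 sinusoidal endothelial markers, 13 fell and 1, the thrombomodulin gene Thbd, chosen after its value was seen, rose, with a median of -1.16. Sinusoidal endothelial genes numbered 1 higher and 15 lower adjusted over the list alone, with a camera adjusted p = 7.06e-06 and an adjusted p = 0.225 with an estimated correlation. The nuclease Dnase1l3 fell from 23.1 ± 6.31 to 0.704 ± 0.115 FPKM (adjusted p = 9.79e-06). The orphan receptor Gpr182 fell from 25.4 ± 9.99 to 1.10 ± 0.930 FPKM (0.593 without knockout 1, adjusted p = 2.48e-04). The lymphatic VEGF receptor Flt4 fell from 9.51 ± 3.08 to 0.992 ± 0.240 FPKM (adjusted p = 2.03e-04).

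Many genes of large vessels and of capillarized sinusoids rose, a difference from the other endothelial lists that was not tested. Of 18 measured, 11 rose and 3 fell (Vwf, Efnb2 and Dll4, named after their values were seen), with a median of 1.13. Large vessel genes numbered 11 higher and 4 lower adjusted over the list alone, with a camera adjusted p = 0.00587 and an adjusted p = 0.413 with an estimated correlation. The adhesion molecule Icam1 rose from 9 ± 2.80 to 40.3 ± 3.79 FPKM (adjusted p = 2.16e-04). The basement membrane collagen Col4a1 rose from 10.6 ± 4.02 to 47.0 ± 6.28 FPKM (adjusted p = 3.98e-04). The chemokine receptor Cxcr4 rose from 1.25 ± 0.449 to 11.8 ± 2.07 FPKM (adjusted p = 1.28e-04). The peptide ligand Apln measured 0 to 0.130 FPKM in control and 4.46 to 4.60 in knockout libraries. Several of these genes are also expressed outside endothelium, such as Icam1 in hepatocytes and leukocytes and Cxcr4 in leukocytes. Control 3 lay nearest the knockout libraries on the first principal component (-34.1 against -49.9 and -50.7 for the other controls). Its mean level of general endothelial genes was 0.34 log2 units above the control mean, and that of macrophage genes 0.50.

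**Figure D2:**
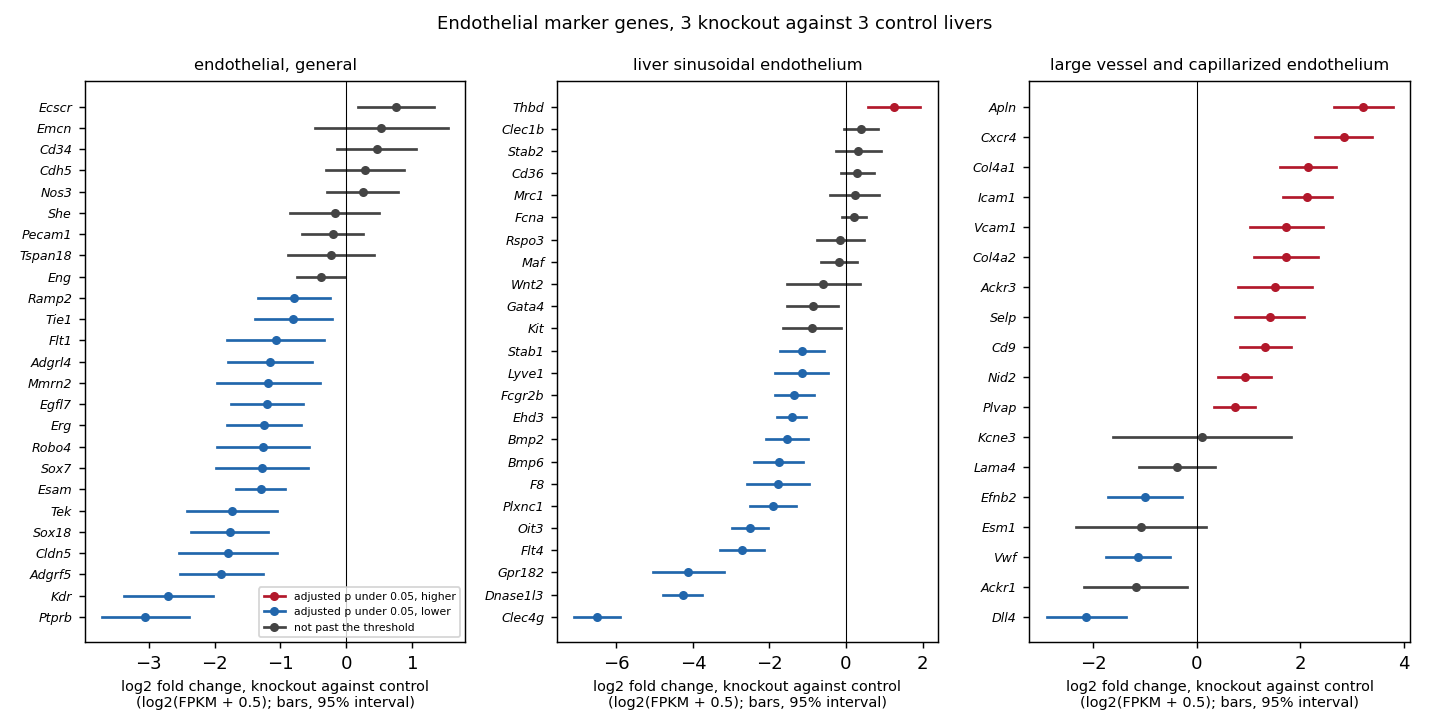
Log2 fold change of knockout against control with its 95% interval for each measured gene of the general, sinusoidal and large vessel endothelial lists, coloured by whether adjusted p was under 0.05 and in which direction. Clec4g, Dnase1l3 and Gpr182 lie at -6.50, -4.26 and -4.12, and Apln and Cxcr4 at 3.22 and 2.84.

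Most genes of the myeloid lists rose. Of 21 neutrophil genes, 20 rose and the remaining gene, G0s2, chosen after its value was seen, measured 26.2 ± 6.47 FPKM in control and 29.5 ± 10.2 in knockout livers, with a median log2 fold change of 3.64. Neutrophil genes numbered 20 higher and 0 lower adjusted over the list alone, with a camera adjusted p = 3.78e-18 and an adjusted p = 0.0445 with an estimated correlation. All 16 monocyte genes rose (median 2.81). Monocyte genes numbered 16 higher and 0 lower adjusted over the list alone, with a camera adjusted p = 9.93e-14 and an adjusted p = 0.0914 with an estimated correlation. Among them the interferon-induced gene Ifitm6 rose from 1.49 ± 0.563 to 39.0 ± 5.30 FPKM (adjusted p = 9.79e-06). The coagulation factor gene F13a1 rose from 0.222 ± 0.102 to 8.69 ± 1.25 FPKM (adjusted p = 2.87e-05). Of 23 macrophage and Kupffer cell genes, 16 rose (median 1.03), among them the lipid receptor Trem2 (log2 fold change 2.35 ± 0.23, adjusted p = 2.03e-04) and the lectin Lgals3 (log2 fold change 2.21 ± 0.34, adjusted p = 0.00168). The lysozyme gene Lyz2 rose from 149.6 ± 99.1 (92.5 without control 3) to 487 ± 58.4 FPKM (adjusted p = 0.00481). Macrophage genes numbered 17 higher and 0 lower adjusted over the list alone, with a camera adjusted p = 7.13e-09 and an adjusted p = 0.223 with an estimated correlation. Lyz2 measured 264 FPKM in control 3, against 99.5 and 85.6 in the other controls. Neutrophil genes were the only list of those tested whose call held with an estimated correlation.

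Some lymphocyte and platelet genes rose as well. Of 15 T and NK cell genes 6 rose, including the interleukin receptor Il7r (0 to 0.144 FPKM in control and 2.25 to 2.85 in knockout libraries). The chemokine Ccl5 rose from 1.95 ± 0.677 to 12.5 ± 4.25 FPKM (adjusted p = 5.79e-04). T and NK cell genes numbered 6 higher and 0 lower adjusted over the list alone, with a camera adjusted p = 0.00298 and an adjusted p = 0.178 with an estimated correlation. Of 11 B and plasma cell genes 7 rose, including the antigen receptor subunits Cd79a (log2 fold change 2.21 ± 0.42, adjusted p = 0.00495) and Cd79b (log2 fold change 2.77 ± 0.46, adjusted p = 0.0026). B and plasma cell genes numbered 7 higher and 0 lower adjusted over the list alone, with a camera adjusted p = 3.14e-04 and an adjusted p = 0.102 with an estimated correlation. B and plasma cell genes called higher numbered 4 without knockout 2 and 4 without knockout 3. Of 7 platelet genes 5 rose, with the platelet chemokine Pf4 going from 3.32 ± 1.36 to 16.3 ± 3.06 FPKM (adjusted p = 6.46e-04). Platelet genes numbered 6 higher and 0 lower adjusted over the list alone, with a camera adjusted p = 0.00386 and an adjusted p = 0.22 with an estimated correlation. Platelet genes called higher numbered 2 without control 1, 1 without control 2, 1 without knockout 1, 3 without knockout 2 and 2 without knockout 3. Of those that rose, Gp9 measured 0 to 0.660 FPKM in control and 0.717 to 2.83 in knockout libraries. Gp9 was not called under 2 alternatives with all 6 libraries (adjusted p of 0.054 to 0.0763), nor without control 2, control 3, knockout 1 or knockout 2 (log2 fold changes of 1.15 to 1.60). Tubb1 measured 0 to 0.848 FPKM in control and 0.736 to 2.99 in knockout libraries. Tubb1 was not called under 4 alternatives with all 6 libraries (adjusted p of 0.0519 to 0.0742), nor without control 1, control 2, knockout 1 or knockout 3 (log2 fold changes of 1.19 to 1.58). Nrgn measured 0 to 0.695 FPKM in control and 1.08 to 2.85 in knockout libraries. Nrgn was not called under 3 alternatives with all 6 libraries (adjusted p of 0.0567 to 0.09), nor without any 1 library other than control 3 (log2 fold changes of 1.01 to 1.56). The mean platelet gene level of control 3 was 0.61 log2 units above the control mean, against -0.44 and -0.17 in controls 1 and 2. Erythroid genes did not shift as a list (5 of 12 higher, 1 lower), but were shifted up under 3 alternatives of that test with all 6 libraries (adjusted p of 0.0187 to 0.0353). Erythroid genes numbered 6 higher and 1 lower adjusted over the list alone, with a camera adjusted p = 0.0548 and an adjusted p = 0.215 with an estimated correlation. Erythroid genes called higher numbered 3 without control 2, 3 without control 3 and 3 without knockout 2. They were also shifted up without control 1, control 2 or knockout 1 (adjusted p = 0.0376, 0.0445 and 0.0208, adjusted p of 0.00963 to 0.321 over all alternatives). The beta globin Hbb-b2, whose reads can be shared with its paralogs, rose from 20.8 ± 8.87 to 58.5 ± 21.4 FPKM (adjusted p = 0.00951).

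Most acute phase genes, which hepatocytes induce in inflammation, rose. Of 31, 22 rose and none fell (median 1.20). Acute phase genes numbered 24 higher and 0 lower adjusted over the list alone, with a camera adjusted p = 2.13e-11 and an adjusted p = 0.0963 with an estimated correlation. The iron-binding lipocalin Lcn2 rose from 240.0 ± 87.0 to 4074 ± 849.5 FPKM (adjusted p = 2.35e-05). The metallothionein Mt2 rose from 169 ± 161 (77.2 without control 2) to 2185 ± 469 FPKM (adjusted p = 0.00105, log2 fold change 4.13, and 3.47 without control 1 and 4.90 without control 2). Saa2 rose from 1749.6 ± 1686 (863 without control 2) to 19938 ± 12199.5 FPKM (adjusted p = 0.0123, log2 fold change 4.13, and 2.86 without control 1 and 5.06 without control 2). Saa2 varied widely among controls, at 168, 3523 and 1558 FPKM, and did not pass with a robust fit (adjusted p = 0.0920, in a range of 0.00764 to 0.092 over all alternatives). Of 27 TNF and NF-kB response genes 15 rose and 1, the caspase-8 inhibitor Cflar, fell. TNF response genes numbered 16 higher and 1 lower adjusted over the list alone, with a camera adjusted p = 4.64e-06 and an adjusted p = 0.178 with an estimated correlation. TNF response genes called higher numbered 8 without knockout 1. The early response gene Ier3 rose from 1.63 ± 1.004 to 12.6 ± 1.73 FPKM (adjusted p = 9.36e-04). The cytokine Il1b rose from 1.47 ± 1.11 (0.926 without control 1) to 8.54 ± 1.71 FPKM (adjusted p = 0.00333). The feedback inhibitor Tnfaip3 rose from 2.17 ± 1.28 (1.44 without control 3) to 11.4 ± 1.54 FPKM (adjusted p = 0.00103). Of 15 chemokines 6 rose and 1, Cxcl12, fell, with Ccl6 rising from 13.7 ± 3.28 to 92.4 ± 23.1 FPKM (adjusted p = 9.65e-05). Chemokines numbered 7 higher and 1 lower adjusted over the list alone, with a camera adjusted p = 0.00275 and an adjusted p = 0.11 with an estimated correlation. Cflar and Cxcl12 lie outside the rule for named genes and were chosen after their values were seen.

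Genes that present antigen rose in part. In the antigen presentation list, 9 of 19 rose and 1, the class I gene H2-Q7, chosen after its value was seen, fell. Antigen presentation genes numbered 11 higher and 1 lower adjusted over the list alone, with a camera adjusted p = 5.12e-04 and an adjusted p = 0.0923 with an estimated correlation. The class II gene H2-Ab1 rose from 39.8 ± 1.29 to 137 ± 2.57 FPKM (adjusted p = 3.17e-05). H2-Eb1 rose from 24.5 ± 2.69 to 79.6 ± 4.26 FPKM (adjusted p = 9.01e-05). H2-Aa rose from 50.9 ± 5.48 to 154 ± 15.1 FPKM (adjusted p = 1.43e-04). Of 30 interferon response genes 8 rose and 1, the immunoproteasome gene Psmb9, also chosen after its value was seen, fell, and the list was not shifted. Interferon response genes numbered 9 higher and 1 lower adjusted over the list alone, with a camera adjusted p = 0.0512 and an adjusted p = 0.575 with an estimated correlation. Interferon response genes called higher numbered 5 without control 1, 4 without control 2, 3 without knockout 1 and 3 without knockout 3. The interferon list was shifted up under 7 alternatives of that test with all 6 libraries (adjusted p of 0.0263 to 0.0497), and without control 1 (adjusted p = 0.0241) or knockout 2 (adjusted p = 0.00231, adjusted p of 0.00231 to 0.575 over all alternatives). The deconjugating enzyme Usp18 rose from 5.09 ± 0.977 to 16.5 ± 1.75 FPKM (adjusted p = 4.30e-04). Ifi27l2a rose from 17.3 ± 3.45 to 47.4 ± 12.9 FPKM (adjusted p = 0.00202). Of 25 cell death genes 9 rose and none fell, among them the death-promoting Bcl2l11 (log2 fold change 1.54 ± 0.27, adjusted p = 0.00323) and Pmaip1 (log2 fold change 1.41 ± 0.27, adjusted p = 0.00529) and the inflammasome sensor Nlrp3 (log2 fold change 1.48 ± 0.31, adjusted p = 0.00694). Cell death genes numbered 10 higher and 0 lower adjusted over the list alone, with a camera adjusted p = 0.00244 and an adjusted p = 0.0963 with an estimated correlation. Of 26 coagulation genes 8 rose and 6 fell. Coagulation genes numbered 10 higher and 7 lower adjusted over the list alone, with a camera adjusted p = 0.664 and an adjusted p = 0.753 with an estimated correlation. Coagulation genes called higher numbered 5 without control 1 and 5 without knockout 3. Coagulation genes called lower numbered 3 without control 2. That list's median was -0.01, with quartiles of -0.41 and 0.63, and its mean of 0.41 rests largely on few large changes. Its camera test, upward, was not past the threshold, though fry's was (adjusted p = 0.0221). The urokinase receptor Plaur rose (log2 fold change 2.32 ± 0.38, adjusted p = 0.00247) and factor VIII, F8, fell (log2 fold change -1.77 ± 0.36, adjusted p = 0.00649).

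Genes induced by low oxygen and genes of glycolysis rose nearly as a whole. Of 25, 24 rose, with a median log2 fold change of 2.02. The remaining one, Eno1, chosen after its value was seen, was listed at 0 in every library but control 3, where it was near 0, and knockout 3. Hypoxia and glycolysis genes numbered 24 higher and 0 lower adjusted over the list alone, with a camera adjusted p = 5.88e-17 and an adjusted p = 0.0914 with an estimated correlation. The vasodilator peptide Adm rose from 2.94 ± 0.858 to 20.9 ± 6.71 FPKM (adjusted p = 2.25e-04). Ankrd37, a target of hypoxia-inducible factor, measured 0 to 0.599 FPKM in control and 13.6 to 23.9 in knockout libraries. The erythropoietin gene Epo was listed at 0 in every control library and at 3.76, 6.66 and 0.844 FPKM in the knockout libraries. Genes of stellate cells and fibrous matrix rose in 18 of 24 cases with none falling (median 1.35). Stellate cell genes numbered 20 higher and 0 lower adjusted over the list alone, with a camera adjusted p = 2.07e-09 and an adjusted p = 0.15 with an estimated correlation. Col1a1, a chain of type I collagen, rose from 5.90 ± 6.06 (2.43 without control 3) to 42.1 ± 16.4 FPKM (adjusted p = 0.00392, log2 fold change 3.10, and 3.84 without control 3). The contractile gene Tagln rose from 5.56 ± 0.273 to 49.0 ± 23.0 FPKM (adjusted p = 2.93e-04). The collagen cross-linking enzyme Loxl2 rose from 1.30 ± 0.566 to 10.3 ± 2.43 FPKM (adjusted p = 2.96e-04).

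Many cell cycle and early response genes rose as well. Of 26 proliferation genes 17 rose and 1, the cyclin Ccnd1, chosen after its value was seen, fell. Proliferation genes numbered 17 higher and 1 lower adjusted over the list alone, with a camera adjusted p = 5.10e-06 and an adjusted p = 0.178 with an estimated correlation. Levels stayed low, with the cyclins Ccna2 and Ccnb2 rising from 0.579 ± 0.577 (0.248 without control 3) to 4.01 ± 0.162 FPKM and from 0.588 ± 0.475 (0.313 without control 3) to 3.72 ± 0.549 FPKM (adjusted p = 0.00217 and 0.002). Of 19 p53 targets 7 rose and 2, Ei24 and Perp, named after their values were seen, fell, and the cell cycle inhibitor Cdkn1a rose from 18.6 ± 4.204 to 125 ± 34.5 FPKM (adjusted p = 8.91e-05). The p53 targets numbered 7 higher and 2 lower adjusted over the list alone, with a camera adjusted p = 0.0128 and an adjusted p = 0.294 with an estimated correlation. Of 22 immediate early and heat shock genes 14 rose and 4 fell. Immediate early genes numbered 14 higher and 5 lower adjusted over the list alone, with a camera adjusted p = 9.81e-05 and an adjusted p = 0.0923 with an estimated correlation. Immediate early genes called lower numbered 2 without control 1, 2 without control 2 and 2 without control 3. The transcription factor genes Egr1 (log2 fold change 3.02 ± 0.29, adjusted p = 2.03e-04) and Junb (log2 fold change 2.63 ± 0.22, adjusted p = 1.16e-04) and the antiproliferative gene Btg2 (log2 fold change 3.37 ± 0.22, adjusted p = 3.07e-05) rose, and the 4 that fell, Hspa1b, Hsph1, Dnajb1 and Hspb1, named after their values were seen, encode chaperones. Genes of endoplasmic reticulum stress did not shift (3 of 23 higher, 1 lower). ER stress genes numbered 2 higher and 1 lower adjusted over the list alone, with a camera adjusted p = 0.549 and an adjusted p = 0.762 with an estimated correlation. Without knockout 2 that list was shifted up (adjusted p = 0.0348, adjusted p of 0.0348 to 0.917 over all alternatives). Atf3, an early response factor, measured 0 to 0.968 FPKM in control and 3.04 to 9.97 in knockout libraries and Herpud1 fell (log2 fold change -0.97 ± 0.19, adjusted p = 0.00474).

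Hepatocyte genes of the central vein side fell more often than those of the portal side, a difference between lists that was not tested. Of 25 pericentral genes 17 fell and 2, Tbx3 and Gulo, both chosen after their values were seen, rose (median -1.05). Pericentral genes numbered 2 higher and 17 lower adjusted over the list alone, with a camera adjusted p = 1.32e-07 and an adjusted p = 0.0914 with an estimated correlation. Glutamine synthetase, Glul, fell from 286 ± 12.9 to 43.4 ± 9.79 FPKM (adjusted p = 2.35e-05). The coumarin hydroxylase Cyp2a5 fell from 322 ± 19.1 to 29.4 ± 1.89 FPKM (adjusted p = 1.35e-06). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 13.9 ± 1.59 to 1.13 ± 0.115 FPKM (adjusted p = 1.97e-05). Cyp2a5 and Cyp2a4 are near-identical paralogs, so their reads may have been split. Of 23 periportal genes 11 fell and 6 rose (median -0.46). Periportal genes numbered 7 higher and 12 lower adjusted over the list alone, with a camera adjusted p = 0.0212 and an adjusted p = 0.38 with an estimated correlation. Periportal genes called higher numbered 3 without control 2. Histidase, Hal, fell from 144 ± 20.2 to 31.4 ± 3.84 FPKM (adjusted p = 4.86e-05) and glucose-6-phosphatase, G6pc, from 111 ± 17.2 to 24.7 ± 12.8 FPKM (adjusted p = 0.00155), while the apolipoprotein Apoa4 rose from 104 ± 16.8 to 1204 ± 848 FPKM (715 without knockout 2, adjusted p = 4.56e-04). The periportal call was lost under 2 alternatives of that test with all 6 libraries (adjusted p of 0.0529 to 0.145), and without knockout 1 (adjusted p = 0.0549, adjusted p of 0.0041 to 0.38 over all alternatives).

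**Figure D3:**
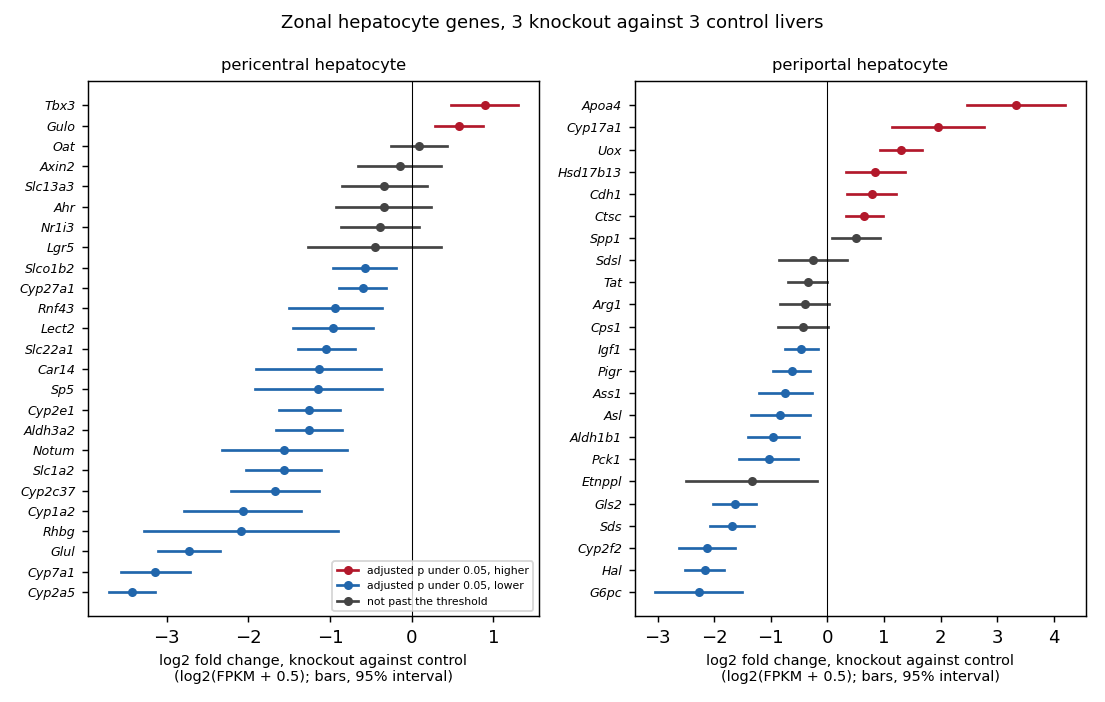
Log2 fold change of knockout against control with its 95% interval for each measured pericentral (left) and periportal (right) hepatocyte gene, coloured by whether adjusted p was under 0.05 and in which direction. Cyp2a5, Cyp7a1 and Glul lie at -3.43, -3.14 and -2.73 on the pericentral side, and Apoa4 and G6pc at 3.33 and -2.28 on the periportal side.

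Many genes of drug, bile acid and sterol metabolism fell. Of 30 cytochrome P450 and drug metabolism genes 18 fell and none rose (median -1.12), among them the glutathione transferase Gstm3 (log2 fold change -2.89 ± 0.28, adjusted p = 2.16e-04) and Cyp2b13 (log2 fold change -2.16 ± 0.42, adjusted p = 0.0051). Drug metabolism genes numbered 1 higher and 20 lower adjusted over the list alone, with a camera adjusted p = 2.58e-08 and an adjusted p = 0.0914 with an estimated correlation. Of 23 bile acid genes 16 fell and none rose (median -0.77). Bile acid genes numbered 0 higher and 17 lower adjusted over the list alone, with a camera adjusted p = 1.32e-07 and an adjusted p = 0.0914 with an estimated correlation. The sterol hydroxylase Cyp8b1 fell from 32.5 ± 12.3 to 8.10 ± 3.07 FPKM (adjusted p = 0.0028). The sterol exporter Abcg5 fell from 39.1 ± 10.01 to 10.8 ± 2.22 FPKM (adjusted p = 6.65e-04). Of 21 cholesterol synthesis genes 17 fell and none rose (median -1.63). Cholesterol synthesis genes numbered 0 higher and 21 lower adjusted over the list alone, with a camera adjusted p = 4.84e-09 and an adjusted p = 0.294 with an estimated correlation. Cholesterol synthesis genes called lower numbered 10 without control 1. Nsdhl fell from 60.7 ± 6.41 to 10.8 ± 6.75 FPKM (adjusted p = 0.00335, log2 fold change -2.70, and -2.004 without knockout 2). Idi1 fell from 19.4 ± 1.93 to 3.97 ± 3.01 FPKM (adjusted p = 0.0126, log2 fold change -2.55, and -1.67 without knockout 2), and the list's mean level in knockout 2 was -2.64 log2 units from the control mean against -1.18 and -0.97 in knockouts 1 and 3.

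Some genes of fatty acid synthesis and of fatty acid oxidation fell. Of 19 fatty acid synthesis genes 8 fell and 1, the nuclear receptor Pparg, chosen after its value was seen, rose, and the elongase Elovl5 fell from 187 ± 13.5 to 55.9 ± 14.8 FPKM (adjusted p = 2.89e-04). Fatty acid synthesis genes numbered 1 higher and 10 lower adjusted over the list alone, with a camera adjusted p = 7.52e-04 and an adjusted p = 0.167 with an estimated correlation. Of 25 fatty acid oxidation genes 12 fell and none rose. Fatty acid oxidation genes numbered 1 higher and 14 lower adjusted over the list alone, with a camera adjusted p = 1.02e-04 and an adjusted p = 0.22 with an estimated correlation. The peroxisomal enzyme Ehhadh fell from 968 ± 29.5 to 356 ± 15.1 FPKM (adjusted p = 1.56e-04). The mitochondrial entry enzyme Cpt1a fell from 79.1 ± 13.5 to 36.7 ± 6.94 FPKM (adjusted p = 0.00258). Of 24 nuclear respiratory chain genes 19 fell and none rose (median -0.69), with Sdhb (log2 fold change -0.99 ± 0.17, adjusted p = 0.00261) and Cyc1 (log2 fold change -0.97 ± 0.14, adjusted p = 0.00138) falling. Respiratory chain genes numbered 0 higher and 20 lower adjusted over the list alone, with a camera adjusted p = 4.84e-09 and an adjusted p = 0.221 with an estimated correlation. In the glucose list 5 of 19 rose and 7 fell. Glucose genes numbered 6 higher and 9 lower adjusted over the list alone, with a camera adjusted p = 0.33 and an adjusted p = 0.66 with an estimated correlation. Its median was -0.35 and its test downward but not past the threshold. Its mean was 0.17, and -0.16 over the 18 genes other than Igfbp1. The insulin receptor substrate Irs2 rose from 0.580 ± 0.447 (0.322 without control 1) to 6.62 ± 0.760 FPKM (adjusted p = 3.16e-04).

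Antioxidant genes fell in 14 of 23 cases and rose in 3. Antioxidant genes numbered 3 higher and 16 lower adjusted over the list alone, with a camera adjusted p = 5.80e-05 and an adjusted p = 0.219 with an estimated correlation. Antioxidant genes called lower numbered 9 without control 2. The members that rose were glutathione peroxidase Gpx3 (log2 fold change 3.54 ± 0.25, adjusted p = 4.68e-05), heme oxygenase Hmox1 (log2 fold change 2.05 ± 0.19, adjusted p = 1.97e-04) and, named after its value was seen, G6pdx of the pentose phosphate pathway. Liver genes that differ between the sexes fell in 13 of 22 cases with none rising, including genes higher in females, such as Cyp2a4 (log2 fold change -2.62 ± 0.44, adjusted p = 0.00263) and Cyp3a44 (log2 fold change -2.60 ± 0.48, adjusted p = 0.00406), and genes higher in males. Sex-biased genes numbered 1 higher and 14 lower adjusted over the list alone, with a camera adjusted p = 5.80e-05 and an adjusted p = 0.11 with an estimated correlation. Of the latter, Elovl3 measured 1.23, 3.84 and 1.14 FPKM in control libraries and was listed at 0 in all knockout libraries. Slco1a1 measured 2.77, 5.403 and 8.78 FPKM in control and 2.54, 0.237 and 0.240 in knockout libraries (adjusted p = 0.0176), and did not pass without control 2, control 3, knockout 2 or knockout 3 (log2 fold changes of -2.22 to -1.89 against -2.25, and -2.93 without knockout 1). Of 20 clock genes 5 rose (Arntl, Npas2, Bhlhe40, Nfil3 and Wee1, all named after their values were seen) and 8 fell, which as a list was not a shift. Clock genes numbered 5 higher and 10 lower adjusted over the list alone, with a camera adjusted p = 0.0828 and an adjusted p = 0.419 with an estimated correlation. Clock genes called higher numbered 3 without control 1, 3 without control 2 and 3 without knockout 2. The clock list was shifted down under 1 alternative of that test with all 6 libraries (adjusted p = 0.0486), and without knockout 2 (adjusted p = 0.0291, adjusted p of 0.0256 to 0.419 over all alternatives). Dbp, Tef and the repressor Nr1d1 fell, Nr1d1 from 36.3 ± 7.85 to 9.81 ± 2.104 FPKM (adjusted p = 3.93e-04) and Tef from 25.5 ± 2.79 to 7.51 ± 2.18 FPKM (adjusted p = 7.13e-04). Estrogen-responsive genes did not shift (4 of 15 higher, 4 lower), with a median of -0.10 and a mean of 0.64, or 0.26 over the 14 genes other than Igfbp1. Estrogen-responsive genes numbered 5 higher and 6 lower adjusted over the list alone, with a camera adjusted p = 0.893 and an adjusted p = 0.946 with an estimated correlation. Estrogen-responsive genes called lower numbered 2 without knockout 3. The cholesterol exporter Abca1 of that list rose from 14.9 ± 4.55 to 46.9 ± 10.4 FPKM (adjusted p = 0.00131), as did the steroid hydroxylase Cyp17a1 (log2 fold change 1.96 ± 0.36, adjusted p = 0.00405).

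Abundant secreted products of hepatocytes did not shift as a list (4 of 26 higher, 6 lower; median -0.09). Secreted product genes numbered 4 higher and 6 lower adjusted over the list alone, with a camera adjusted p = 0.288 and an adjusted p = 0.66 with an estimated correlation. Secreted product genes called higher numbered 1 without control 1, 1 without control 2, 1 without knockout 1 and 2 without knockout 3. Secreted product genes called lower numbered 2 without control 1 and 3 without control 2. Transferrin, Trf, rose from 11753 ± 1011 to 26839 ± 3497 FPKM (adjusted p = 0.00506) and transthyretin, Ttr, fell from 6049 ± 1164 to 2527 ± 109.9 FPKM (adjusted p = 0.00198). Trf did not pass with quantile normalization (log2 fold change 0.18, adjusted p = 0.503) or without a filter (adjusted p = 0.0606, in a range of 5.68e-04 to 0.503 over all alternatives). Bile duct genes did not shift (2 of 9 higher, 2 lower), while Cd24a rose from 1.07 ± 0.818 (0.659 without control 3) to 13.8 ± 2.83 FPKM (adjusted p = 4.40e-04) and Sox9 (log2 fold change 1.34 ± 0.31, adjusted p = 0.0126). Bile duct genes numbered 3 higher and 2 lower adjusted over the list alone, with a camera adjusted p = 0.598 and an adjusted p = 0.66 with an estimated correlation. The bile duct keratins Krt19 and Krt23 went the other way, while the keratin Krt7, chosen after its value was seen, was not called. Krt19 measured 2.45 to 4.21 FPKM in control and 0 to 1.499 in knockout libraries (adjusted p = 0.0353), and did not pass without any 1 control or without knockout 1 (log2 fold changes of -1.80 to -1.39), or under 3 alternatives with all 6 libraries (adjusted p of 0.0511 to 0.0794). Without knockout 3 the log2 fold change of Krt19 was -1.01, against -1.60 with it. Krt23 measured 0.569 to 2.24 and 0 to 0.329 FPKM (adjusted p = 0.0327), and did not pass without control 1, control 2, knockout 1 or knockout 3 (log2 fold changes of -1.49 to -1.10). Mesothelial genes did not shift either (1 of 9 higher, 3 lower), with Upk3b (log2 fold change -1.32 ± 0.27, adjusted p = 0.00699) and Igfbp5 (log2 fold change -1.67 ± 0.36, adjusted p = 0.00853) falling and the keratin Krt18, which hepatocytes also express, rising (log2 fold change 0.92 ± 0.19, adjusted p = 0.00664). Mesothelial genes numbered 2 higher and 4 lower adjusted over the list alone, with a camera adjusted p = 0.197 and an adjusted p = 0.419 with an estimated correlation. Of 22 ribosomal protein genes only Rps9 passed (log2 fold change 0.52 ± 0.16, adjusted p = 0.0392), a call lost without any 1 library but knockout 1, with log2 fold changes of 0.43 to 0.57, and under 4 alternatives with all 6 libraries (adjusted p of 0.0589 to 0.0817). Rpl8, with a log2 fold change 0.33 ± 0.15, passed with quantile normalization (adjusted p = 0.0112, in a range of 0.0112 to 0.29 over all alternatives), and many members share reads with pseudogenes. Ribosomal protein genes numbered 0 higher and 0 lower adjusted over the list alone, with a camera adjusted p = 0.0432 and an adjusted p = 0.575 with an estimated correlation. The list's call was lost under 5 alternatives of that test with all 6 libraries (adjusted p of 0.0559 to 0.105), and without control 3 (adjusted p = 0.235), knockout 2 (adjusted p = 0.0998) or knockout 3 (adjusted p = 0.0921, adjusted p of 6.09e-05 to 0.575 over all alternatives). Of pancreatic genes 2 were measured, Cela2a (0 to 0.592 FPKM in control and 1.86 to 4.27 in knockout libraries) and Cela1, which fell (log2 fold change -1.51 ± 0.24, adjusted p = 0.00206). Pancreatic genes numbered 1 higher and 1 lower adjusted over the list alone. Of gut, fat and muscle genes 4 were measured and 2 fell, Car3, also abundant in hepatocytes, and Fabp2 (log2 fold change -0.85 ± 0.26, adjusted p = 0.0386), the latter not past the threshold without any 1 library but knockout 3 (log2 fold changes of -0.95 to -0.69) or under 4 alternatives with all 6 libraries (adjusted p of 0.0539 to 0.0719). Gut, fat and muscle genes numbered 0 higher and 3 lower adjusted over the list alone. No gene of the mitochondrial genome list was measured, and these 3 lists were too small to test.

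Of the 41 lists tested, 30 were shifted with the preset correlation of 0.01 and 1 with an estimated correlation. Splitting the same 6 libraries into 3 and 3 in any other way shifted 12 to 22 lists with the preset correlation. Those splits mix the groups unequally and so keep part of the difference between them.

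**Figure D4:**
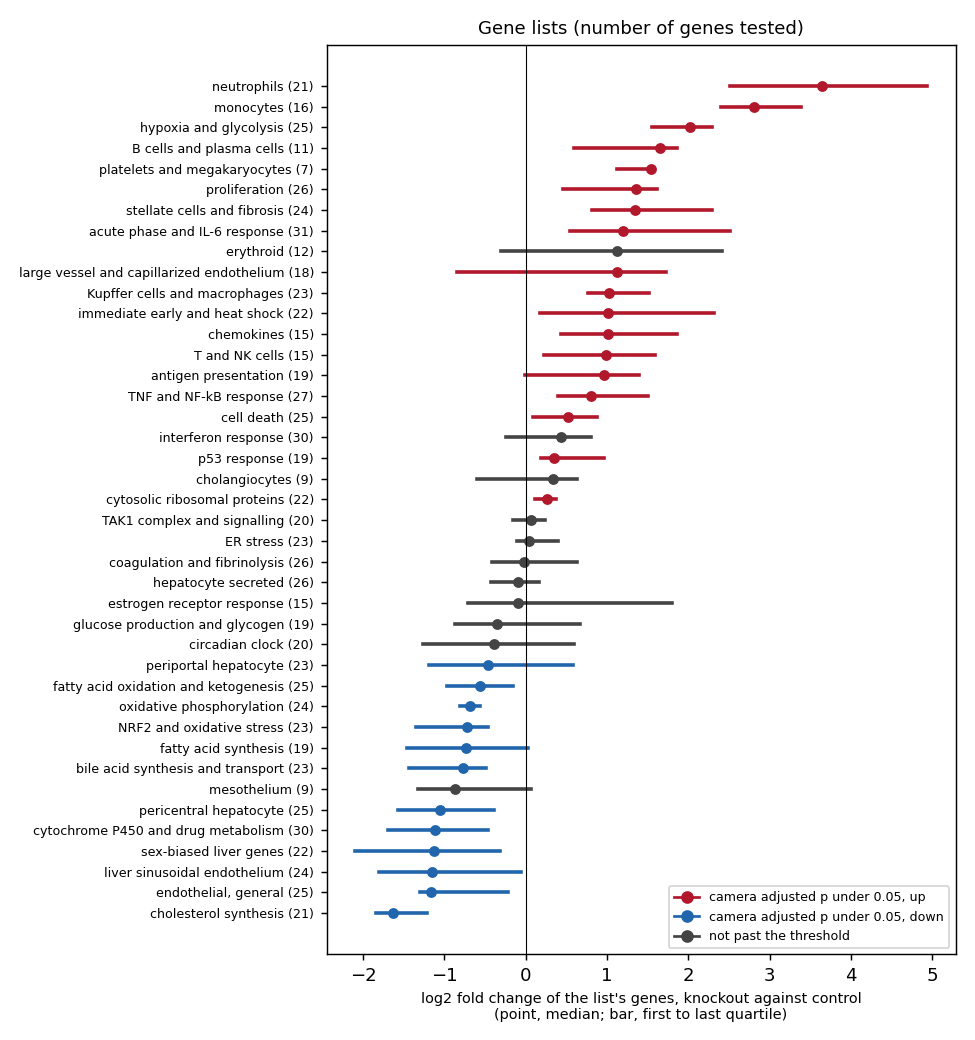
Median log2 fold change (point) and interquartile range (bar) of the genes of each of 41 tested lists, with the number of genes tested in brackets, coloured by the camera test with a preset correlation. 18 lists were shifted up and 12 down. Neutrophil and monocyte genes stand highest with medians of 3.64 and 2.81, and cholesterol synthesis lowest with -1.63.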

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

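The alternatives that kept Alb, removed genes at 0 in any library or removed the length and GC trend were chosen after seeing the data. The counts kept within 1.5 times their reported values (1669 higher, 1534 lower) under every alternative that used all 6 libraries: 1323 to 1860 genes were higher and 1287 to 2076 lower. Without 1 library the lower genes ranged from 943 (without control 2) to 1497 and the higher from 1186 to 1644. Beside each list the report gives calls without 1 library where a count of at least 4 moved more than 1.5 times. Map3k7 stayed short of the threshold throughout, with log2 fold changes of -0.16 to 0.06. Of the 30 lists shifted, 1 was shifted with an estimated correlation; between 26 and 32 were shifted under the other alternatives. Correlation between genes alone does not give the lower count. The antigen presentation, chemokine and cell death lists had estimated correlations of 0.0028, 0.0079 and -0.015, below the preset 0.01. Their unadjusted camera p still rose, from 2.6e-04, 0.0016 and 0.0014 to 0.018, 0.033 and 0.023. With an estimated correlation, camera takes its p-values from the few residual degrees of freedom that 6 libraries leave. With the preset correlation it takes them from the number of genes tested. That difference raises p at any correlation, and its share in the lower count was not tested. Same-numbered libraries deviated from their group means with correlations of -0.010, -0.00012 and 0.0015, against 0.033 for control 1 with knockout 3. By Spearman correlation knockout 1 lay nearest each of controls 1, 2 and 3 (0.945, 0.943 and 0.951). These values give no sign that the numbers pair the samples, but correlations this weak cannot exclude it. With a replicate block 1575 genes were higher, 1385 lower, 31 lists shifted and Map3k7 was at -0.04. Of 158 named genes past the threshold, 132 stayed past it in every alternative that tested them and none reversed. Stricter filters and the removal of zeros left some named genes untested, and those have no value there. Depth limits genes near 0.5 FPKM, where 1 fragment can set a value.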

Other observations

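The tests of explanations and of other splits, and the genes named here other than Igfbp1, Irs2, Thrsp and G6pc, were chosen after the results were seen. No group of these genes was tested. The eosinophil ribonuclease genes Ear1 and Ear6 were listed at 0 in every control library and at 12.9, 5.86 and 6.79 and 15.9, 7.53 and 6.79 FPKM in the knockout libraries, with zeros that can be failed estimates. Their paralog Ear2 rose from 10.4 ± 4.26 to 44.4 ± 7.10 FPKM (adjusted p = 5.97e-04). The eosinophil peroxidase gene Epx was listed at 0 in controls and at 2.72, 1.25 and 2.36 FPKM in knockouts. The granule genes Mpo and Prtn3 rose, Mpo from 0.618 ± 0.605 (0.272 without control 3) to 17.8 ± 3.02 FPKM (adjusted p = 9.65e-05) and Prtn3 from 59.3 ± 13.9 to 169.7 ± 20.0 FPKM (adjusted p = 4.83e-04), while Ctsg measured 0 to 1.41 FPKM in control and 12.7 to 16.3 in knockout libraries. The Ear genes are near-identical copies and can share reads.

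Globin values switched between paralogs from library to library: Hba-a1 measured 81.8, 67.0 and 42.8 FPKM in control and 0.221, 0.611 and 313 in knockout libraries, and Hba-a2 0.105, 0.0983 and 0.0946 and 119, 238 and 0.105. The nuclear RNA Malat1 measured 14.3, 23.2 and 5.06 FPKM in control and 17.6, 3.29 and 2.75 in knockout libraries, and Neat1 4.88, 4.2 and 0.643 and 6.81, 2.83 and 2.12. The hepcidin gene Hamp2 fell from 77.3 ± 39.0 to 6.06 ± 3.76 FPKM (adjusted p = 0.00187) while its paralog Hamp measured 442 ± 218 FPKM in control and 338 ± 79.3 in knockout livers.

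Chance in the grouping of the libraries cannot be put under 0.05 with the 10 splits of 6 libraries into 3 and 3. The real split gave 1669 higher and 1534 lower genes, and the highest number in 1 direction among the other splits was 1. The real split, the only one of 10 to do so, shifted 30 lists, and the highest of the others shifted 22. Every other split has libraries of both groups on each side in unequal numbers, so part of the real difference stays in it. Such splits therefore cannot show how many genes or lists would be called without a difference.

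Endothelial markers moved apart: some fell steeply and others did not fall. Loss of all endothelial cells alike would lower the general markers together, but 13 of 25 had a 95% interval wholly away from the list's median, 9 of them above it. General markers also made by other liver cells would fall less, and the list does not mark which these are. Cdh5, the gene whose promoter drives the Cre, did not fall, while 16 of the 25 did. Its log2 fold change was 0.28 (95% interval -0.31 to 0.87), wholly above the list's median of -1.16. A single gene does not settle the question, so such a loss stays open. Low values and the pseudocount do not account for all of it: among the 11 members with at least 5 FPKM in controls, at a pseudocount of 0.1, 6 had an interval wholly away from the median of those 11. Loss of sinusoidal cells alone may be part of it and stays open: 14 of 24 sinusoidal members lay away from their median, but members made by other liver cells would fall less. A changed program of the endothelial cells that remain after deletion of TAK1, the difference the design names, was not tested.

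Many hepatocyte metabolic genes fell. Over the 175 genes of 8 lists (pericentral, periportal, drug, bile acid, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and glucose) 100 were lower and 14 higher, with a median log2 fold change of -0.87. A smaller share of hepatocyte RNA would lower the abundant secreted products as much, but 19 of 26 had a 95% interval wholly above that median (15 to 20 without 1 library). Among the secreted products only Fgb is also in the acute phase list, of which 22 of 31 rose. A rise of that kind could offset a smaller share for Fgb, but the lists give no such ground for the other products. These values argue against a smaller share alone, while a smaller share as a part of the cause stays open. Less feeding alone would raise fatty acid oxidation genes, and 12 of 25 were lower and 0 higher (8 to 13 lower without 1 library, and 1 higher without knockout 1). That list's shift was not called with an estimated correlation (adjusted p = 0.22). Less feeding as a part of the cause stays open. The fall of 17 of 21 cholesterol synthesis genes (10 without control 1) and of 8 of 19 fatty acid synthesis genes goes with it, as do the fall of Thrsp (log2 fold change -3.67 ± 0.28, adjusted p = 6.32e-05) and the rise of Irs2 (log2 fold change 2.79 ± 0.30, adjusted p = 3.16e-04) and Igfbp1 (log2 fold change 6.03 ± 0.47, adjusted p = 7.51e-05). Irs2 and Igfbp1 are members of the glucose list, of which 5 of 19 rose and 7 fell. Among those that fell was G6pc (log2 fold change -2.28 ± 0.34, adjusted p = 0.00155). Tamoxifen itself could contribute and cannot be told apart from the deletion, since 0 of 3 control libraries are labelled as given tamoxifen. The deletion of TAK1 stays among the open explanations.

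Clock genes moved in opposite directions, 5 higher and 8 lower (3 higher without control 1, control 2 or knockout 2). Collection at another time of day could give such a pattern. The labels of 0 of 6 libraries give a collection time, so it cannot be told apart from an effect of the deletion or of tamoxifen.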
